A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

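The series measured splicing in wild-type fission yeast, Schizosaccharomyces pombe, by multiplexed primer extension sequencing (MPE-seq). In this targeted form of RNA sequencing, gene-specific primers placed close to introns start reverse transcription on many transcripts at once, so that reads are spent on splice junctions and introns. Per the labels, the strain was a Bioneer wild type grown in YES, a rich medium, at 30 °C to an OD600 of 0.8 in log phase. Total RNA was extracted with phenol and chloroform, and libraries followed a published MPE-seq protocol, per the labels' protocols. There are 2 libraries in 1 group, called wild-type replicate 1 and replicate 2 after the letters in their titles. The labels do not say whether the libraries came from separate cultures. Differences between them therefore measure only the spread between these libraries, which may be technical.

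The deposited files hold raw counts, whole numbers per gene in the classes exonic, mature and premature, for 1144 genes in each library, per the file headers. The submitters' processing notes name Trimmomatic 0.35, HISAT2 2.1.0 and HTSeq, with no version for HTSeq and no role or order for any of them. How each class was defined, the genome build, the annotation, the strand setting and any use of molecular identifiers are not given in the sources used here. The mature class was read as spliced and the premature class as unspliced, from their names. Exonic counts are not a sum that contains the mature counts, since they lay below the mature count in 4 genes of replicate 1 and 6 genes of replicate 2. Without a known strand setting, reads of a gene and of an overlapping or antisense partner cannot be told apart. Reads of near-identical ribosomal protein gene copies could have been split between them, so values of such copies are uncertain.

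The main measurement was the unspliced percentage, the premature count divided by the sum of mature and premature counts of a gene. Genes with a sum under 50 in either library were left out, which removed 280 genes and kept 864. Values are the mean ± SD of both libraries. Single-library values carry 95% Wilson intervals, and a count of 0 was given an upper limit of 3 counts. Intervals and limits cover counting error only. Whether molecular identifiers were used is not known, and without them amplified reads are not independent molecules. Exonic counts were scaled to the library total. The larger library held 10009017 exonic counts and the smaller one 5796068.

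With 1 group and no second condition, the comparisons were of library against library and of genes against other genes within a library. Mature and premature counts of each gene were compared between the libraries with a two-sided Fisher exact test. Exonic counts of at least 50 in each library were compared with a two-sided exact binomial test. Both were adjusted by Benjamini-Hochberg at 0.05 over all genes tested, and also over each list alone. These tests compare 2 libraries with counting noise and do not compare conditions. edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3 supplied alternative scaling factors and no test. Calculations used Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.

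Gene lists were patterns of gene symbols for ribosomal proteins, splicing factors, meiosis and sporulation, proteasome and ubiquitin, cytoskeleton and division, small GTPases and vesicle traffic, mitochondrial respiration, transcription machinery, and structural and organelle RNA. The lists, tests, count minimum and most alternatives were fixed before the data were examined. The median of each list was placed among 10000 random lists of the same size, drawn from all measured genes, list members included, and matched on the sum of mature and premature counts in 10 bins. A list is said to stand apart when its percentile was at most 2.5 or at least 97.5. This describes these libraries and is not a test across replicates. Lists with under 5 measured members were not compared.

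Gene symbols, intron lengths, splice sites and intron locations came from the RefSeq annotation of assembly ASM294v3, matched on the systematic gene ID regardless of letter case. Of the 1144 genes, 1141 matched and 3 did not. Gaps between exons under 20 nt were not counted as introns. The annotation held exactly 1 intron in 1078 genes, no intron in 61 and over 1 intron in 2. The 61 genes included 21 whose exons abut, overlap or lie under 20 nt apart. The deposited counts do not say which intron each value belongs to, and the authors' build is unknown, so no start or end coordinates are printed. Where a gene had 1 annotated intron, its value was taken to refer to that intron. The groups by intron location, and the comparison of gene copies, were chosen after the values had been seen.

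The genes named in the text followed a rule set beforehand. It took the 10 highest and the 10 lowest mean unspliced percentages, the 5 largest sums of mature and premature counts, the 5 largest differences among genes past the Fisher test, and the highest and lowest member of each list. Ties were ordered by the larger sum. Other genes named as examples were chosen after their values were seen.

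The tests were run on simulated data before use. For mature and premature counts of 864 genes, 200 genes were given an odds ratio of 3, of which 127 (63.5%) were recovered, with 2 unchanged genes called. For exonic counts of 1093 genes, 198 of 200 genes changed 1.5-fold were recovered, with 8 unchanged genes called. The simulated libraries held counting noise only. Between the real libraries the chi-square per degree of freedom was 40.2 for exonic counts and 4.97 for mature and premature counts. The simulated rates therefore do not carry over to the real libraries. Alternatives were minimums of 20 and 200 or none, 0.5 added to both counts, summed counts, each library alone, TMM and DESeq2 scaling, a test scaled by overdispersion, list means, and unmatched random lists. Chosen after seeing the data were restriction to genes with 1 RefSeq intron, omission of the ribosomal protein genes, and random lists matched on exonic count.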

Results

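MPE-seq counts of mature and premature transcripts were obtained for 1144 genes in 2 wild-type fission yeast libraries, replicate 1 and replicate 2. The series asked how precisely this targeted assay measures spliced transcripts and rare unspliced precursors. Replicate 1 held 5796068 exonic, 634306 mature and 53090 premature counts. Replicate 2 was deeper, with 10009017 exonic, 1194460 mature and 82204 premature counts. Of the mature and premature counts together, 7.72% were premature in replicate 1 (95% Wilson interval 7.66 to 7.79) and 6.44% in replicate 2 (6.40 to 6.48). The median gene had 126 mature and premature counts in replicate 1 and 190.5 in replicate 2, and 51 and 50 genes had none. The 65 ribosomal protein genes took 31.1% of all exonic counts in replicate 1 and 34.6% in replicate 2.

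Most transcripts were largely spliced. Across the 864 genes with at least 50 counts in each library, the median unspliced percentage was 7.76% in replicate 1 and 7.39% in replicate 2. On the mean of both libraries the middle of the distribution ran from 2.65% (lower quartile) to 20.3% (upper quartile). There were 330 genes (38.2%) under 5% unspliced and 93 under 1%. At the other end, 85 genes (9.84%) lay above 50% and 35 above 90%. Of these, 16 and 13 respectively had no RefSeq intron of 20 nt or more. Of the 85, 68 had 1 RefSeq intron. The median SD between the libraries was 1.02 percentage points. The median depended on the count minimum, and was 3.89% among genes with at least 200 counts.

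The lowest values included 5 genes with no premature read at all. No premature read was counted in either library for gap1 (SPBC646.12c), which encodes a Ras GTPase-activating protein, against 1866 and 3057 mature counts. This allows a share of up to 0.161% in replicate 1 and 0.0981% in replicate 2. The genes mrpl24 (SPBC14C8.10), ats1 (SPAC10F6.04), yap18 (SPBC19F8.03c) and hmt1 (SPCC737.09c) were also at 0 premature counts in both libraries. For hmt1, with 77 mature counts in each library, a share of up to 3.90% remains possible. The ribosomal protein gene rpl1602 (SPAC23A1.11) was at 0.0860% ± 0.00807 (SD, n = 2), with 5445 and 11194 mature counts. The others among the 10 lowest were tuf1 (SPBC9B6.04c), a mitochondrial elongation factor, at 0.104% ± 0.147, int6 (SPBC646.09c), a translation initiation factor subunit, at 0.180% ± 0.135, bpb1 (SPCC962.06c), a branch point binding protein, at 0.192% ± 0.272, and the AAA ATPase gene cdc48 (SPAC1565.08) at 0.202% ± 0.00683.

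The highest values were 100% in both libraries, with no mature read in 11 genes. The 10 with the most counts were SPBC337.02c, SPBC409.08, med11 (SPAC644.10), cwf22 (SPBC13E7.01), ppt1 (SPAC56F8.04c), SPBC1E8.02, new11 (SPAC23A1.20), mmb1 (SPBC25B2.07c), SPAPB24D3.05c and trp663 (SPCC663.14c). For SPBC337.02c, 307 and 550 premature counts without a mature read allow an unspliced share as low as 99.0% in replicate 1 and 99.5% in replicate 2. Of these 10 genes, SPBC337.02c, cwf22, ppt1, new11, mmb1 and SPAPB24D3.05c had no intron of 20 nt or more in the RefSeq annotation. The Mediator subunit gene med11 (chromosome I) had a coding intron of 60 nt with the 5′ splice site GTAAAT. SPBC409.08 (chromosome II) had a coding intron of 42 nt that began with GTTGGA, whereas GTAAGT began 381 of the 1078 single introns in the annotation. SPBC1E8.02 had an intron of 80 nt in its 3′ UTR, and trp663 a coding intron of 89 nt beginning with GTAAGT.

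**Figure D1:**
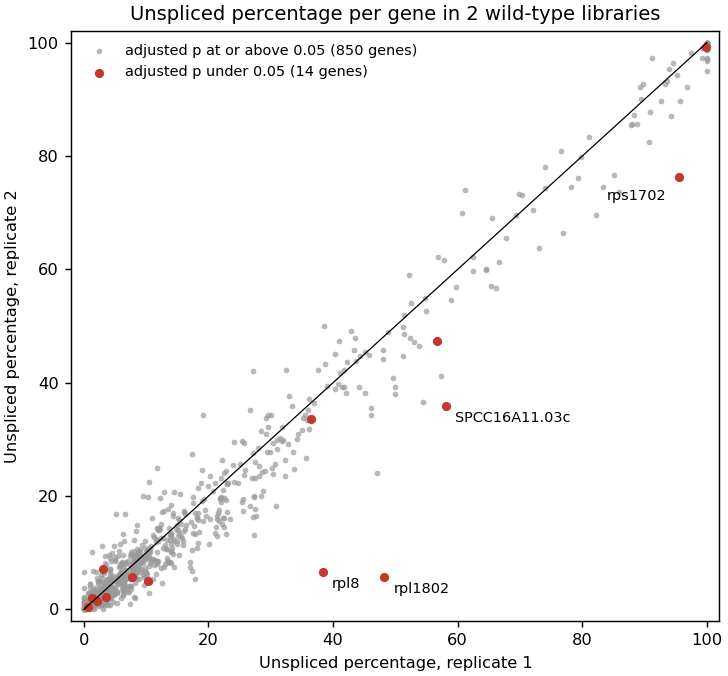
Unspliced percentage of each of 864 genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis) of wild-type fission yeast, with the line of equal values. Points in red mark the 14 genes past the Fisher exact test, and the 4 labelled genes differed by over 10 percentage points.

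Both libraries ordered the genes alike. Across genes, which are not independent replicates, the unspliced percentage had a Spearman rho of 0.950 between libraries and its logit a Pearson r of 0.968. Exonic counts had a Pearson r of 0.998 on the log2 scale. For the 455 genes whose smaller library held 50 to under 200 counts, the root mean square difference between libraries was 4.90 percentage points, against 4.30 from counting noise. For 306 genes with 200 to under 1000 counts it was 3.42 against 1.98, and for 103 genes with 1000 counts or more it was 3.77 against 0.432. Much of the excess in the last 2 classes rests on a pair of genes in each. Without rpl1802 and SPBC1711.15c the value for 200 to under 1000 counts was 2.31, and without rpl8 and rps1702 the value for 1000 counts or more was 0.934.

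The unspliced percentage differed between the libraries in 14 of 864 genes by the two-sided Fisher exact test at an adjusted p under 0.05, with 2 higher and 12 lower in replicate 2. At an unadjusted p under 0.05 there were 89. Of the 14 genes, 9 encode ribosomal proteins, out of 65 tested, and 13 of the 65 passed when adjusted over the list alone. In every other list compared, no gene passed either way. Ribosomal protein genes had a median sum of 14889 counts over both libraries, against 223 to 917 in those lists. Smaller differences could therefore pass among ribosomal protein genes. The largest difference was in rpl1802 (SPAPB17E12.13), a large subunit protein gene, with 48.2% unspliced in replicate 1 (44.8 to 51.7) and 5.68% in replicate 2 (4.24 to 7.56), at an adjusted p of 7.74e-86. Its premature count was 397 in replicate 1 and 43 in the deeper replicate 2. In rpl8 (SPBC29A3.04), 38.4% (36.8 to 40.0) stood against 6.62% (5.99 to 7.30), at an adjusted p of 1.41e-306. In SPCC16A11.03c, 58.1% (49.3 to 66.4) stood against 35.9% (29.3 to 43.0), at an adjusted p of 0.0137. In rps1702 (SPCC24B10.09), a small subunit protein gene, 95.5% (94.5 to 96.3) stood against 76.4% (75.1 to 77.5), and its mature count was 94 in replicate 1 and 1161 in replicate 2. The gene prs5 (SPBC3D6.06c) differed by less than 10 points, at 56.6% and 47.3%. All 5 lay in coding sequence, with introns of 71, 66, 308, 64 and 422 nt in that order. The call depends on the noise model, since 3 genes passed when the test was scaled by the overdispersion between the libraries. That factor was the mean chi-square over 676 genes, 4.97. The genes with the largest differences were among them and raised it. A median-based overdispersion was 1.65, and the number of genes passing at that scale was not tested.

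Exonic counts also differed between the libraries by more than counting noise, by amounts and in numbers of genes that depended on the scaling and the noise model. Scaled to the library totals, the exact binomial test called 795 of 1093 genes, 96 higher and 699 lower in replicate 2. Scaled by the overdispersion between the libraries, which was estimated with the called genes included, 18 were called. The median log2 ratio of replicate 2 over replicate 1 was -0.13 when scaled to the library totals. With DESeq2 size factors, which are built to bring it near 0, it was 0.00, and there were 403 calls, 254 higher and 149 lower. Ribosomal protein genes had a median log2 ratio of 0.16, which is 0.29 above the median of all genes, and 62 of 65 lay above that median. Of these 65 genes, 55 passed as higher and 4 as lower, 59 in all both over all genes and when adjusted over the list alone. With DESeq2 size factors, 62 were higher and 1 lower. Random lists matched on exonic count had a median of 0.05, and the ribosomal protein median stood at percentile 100. The other lists had medians from -0.18 (meiosis and sporulation) to -0.10 (cytoskeleton and division), none of them outside percentiles 11.1 to 79.6. In these lists, 19 of 25 splicing factor genes, 20 of 40 meiosis genes, 11 of 17 proteasome genes, 9 of 13 cytoskeleton genes, 18 of 25 GTPase and traffic genes, 28 of 38 mitochondrial genes and 12 of 18 transcription genes passed. Adjusted over the list alone the counts were equal except for 19 GTPase and traffic genes. Among single genes, 3 differed by more than 1.5-fold when scaled to the library totals. The fatty acid elongase gene elo2 (SPAC1B2.03c) had a log2 ratio of 0.73, with 1287 and 3679 exonic counts. The retrotransposon Tf2-10 (SPBC1E8.04) had -0.76 with 51 and 52 counts, and mug45 (SPBP8B7.04) had -0.59. With DESeq2 size factors mug45 was at -0.46, under 1.5-fold, and the ribosomal protein gene rpp201 (SPBP8B7.06) at 0.61 was over it.

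**Figure D2:**
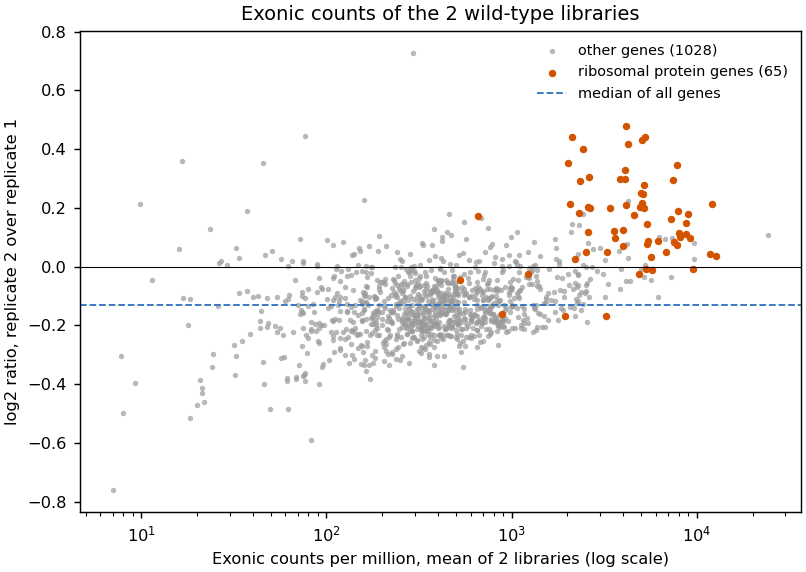
Log2 ratio of exonic counts, replicate 2 over replicate 1, scaled to the library totals, against the mean library-scaled exonic counts on a log axis, for 1093 genes. The 65 ribosomal protein genes (orange) have a median of 0.16 and the dashed line marks the median of all genes at -0.13.

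Genes named for meiosis, sporulation or mating were the least spliced of the lists fixed beforehand. The median of their 23 measured members was 63.9%, against 11.2% for random lists matched on count, at percentile 100 on the mean and in each library. The list held 12 members above 50% and 6 above 90%. The highest was the meiotic recombinase gene dmc1 (SPAC8E11.03c) at 99.4% ± 0.907 (SD, n = 2), with 65 and 77 premature and 0 and 1 mature counts. Equal to it, with fewer counts, was mfr1 (SPBC1198.12), an activator of the anaphase-promoting complex in meiosis. Further values were 94.5% ± 3.27 for mde2, which acts in meiotic DNA break formation, and 94.3% ± 4.29 for bqt1, which acts in telomere clustering. Other members were spliced: the pheromone receptor gene map3 (SPAC3F10.10c) was lowest at 0.838% ± 0.0598, and bqt3 was at 3.76% ± 0.439. RefSeq holds no intron of 20 nt or more in map3, so its value cannot be tied to an annotated intron. The symbol pattern also took in mam33 and slx9, which are not known as meiosis genes, at 5.97% and 34.5%. Another 20 of the 43 list members in the files were below the count minimum.

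Ribosomal protein genes were largely spliced, with a median of 1.02% over 65 genes and 54 of them under 5%. Against random lists matched on count, with a median of 1.14%, the percentile was 2.58, above the cut of 2.5, so the list did not stand apart by the rule set beforehand. That comparison says little, because 61 of the 87 genes in the bin with the highest counts belong to the list. The percentile was 0 against unmatched random lists, and 0.0250 against lists matched on exonic count, an alternative chosen after seeing the data. It was 63.6 with list means and 15.6 at a minimum of 200 counts. The most counted genes were rps21 (SPBC18E5.06) at 0.449% ± 0.0716, rpl31 (SPAC890.08) at 0.408% ± 0.0394, rpl4101 (SPAC3G6.13c) at 0.443% ± 0.119 and rps1802 (SPCC1259.01c) at 0.353% ± 0.0708. The fifth, rpl39 (SPCC663.04), was at 35.0% ± 2.06, with 4418 and 9046 premature counts. The annotation places its intron of 62 nt in the 3′ UTR. Besides rps1702, at 85.9% ± 13.5, the list members above 50% were rpl102 at 58.3% ± 1.95 and rpl3002 at 50.2% ± 3.13.

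Proteasome and ubiquitin genes had a median of 2.05% over 13 genes, against 6.86% for random lists, at percentile 0.325. In replicate 1 alone the percentile was 3.47, and at minimums of 20 and 200 it was 9.45 and 2.60, so this call was not stable. The ATPase gene rpt2 (SPBC4.07c) was lowest at 0.221% ± 0.312. The ubiquitin-conjugating enzyme gene ubc16 (SPBC1198.09) was highest at 17.2% ± 1.35.

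Like the ribosomal protein list, the remaining lists did not stand apart by that rule. Splicing factor genes had a median of 7.25% over 20 genes (percentile 23.5), from bpb1 at 0.192% to cwf22 at 100%. The U2 snRNP protein gene lea1 was at 91.2% ± 2.03 and syf2 at 79.8% ± 8.60, while the Sm protein gene smb1 was at 0.993% ± 0.00436. Cytoskeleton and division genes had a median of 3.39% over 11 genes (percentile 16.0), with the actin-related gene arp2 (SPAC11H11.06) at 0.587% ± 0.00600 and the microtubule-binding protein gene mal3 (SPAC18G6.15) at 29.9% ± 2.17. Small GTPase and traffic genes had 4.43% over 21 genes (percentile 16.5), from apl6 (SPAC23H3.06) at 0.276% ± 0.0455 to vps901 (SPBC4F6.10) at 99.1% ± 0.117. Mitochondrial genes had 5.62% over 34 genes (percentile 48.1), from mrpl24 at 0% to mrps9 (SPAC29A4.03c) at 99.8% ± 0.274. Transcription machinery genes had 9.99% over 16 genes (percentile 63.7), from the TFIIH subunit gene tfb2 (SPBC13G1.13) at 1.16% ± 0.425 to med11 at 100%. None of cwf22, vps901, mrps9 and mrpl24 has a RefSeq intron of 20 nt or more. The list for structural and organelle RNA caught 4 protein-coding genes by their symbols and was not compared, with rrn11 (SPBC725.17c) lowest at 8.21% ± 0.515 and rrn3 (SPAC18G6.11c) highest at 40.1% ± 2.66.

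**Figure D3:**
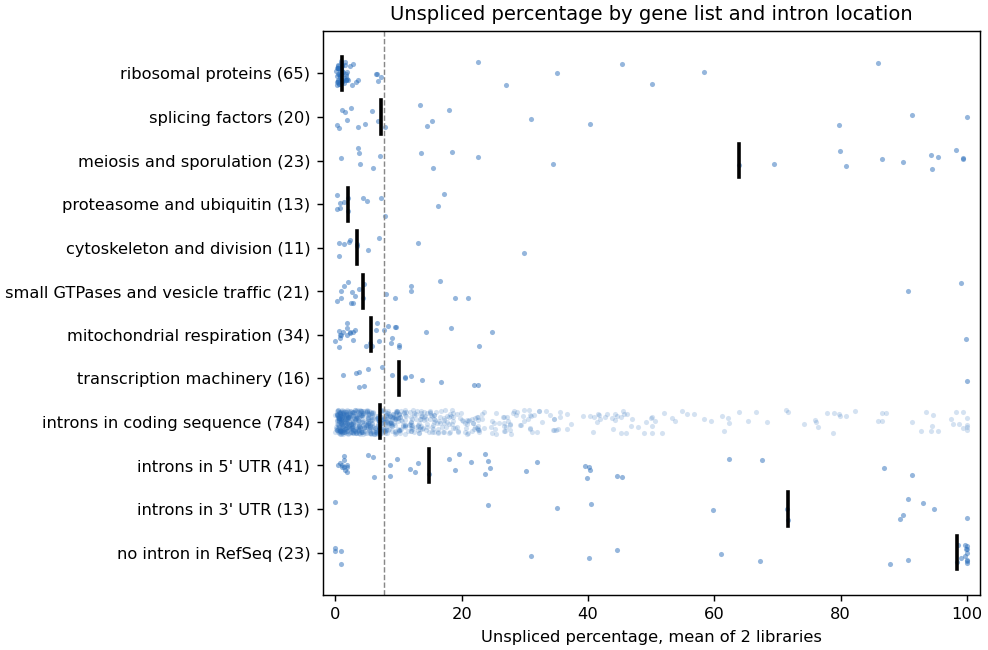
Unspliced percentage (horizontal axis, mean of both libraries) of each measured gene in the lists and in genes grouped by the location of their RefSeq intron, with the number of genes in parentheses. Black bars mark medians, such as 63.9% for meiosis and sporulation and 71.6% for 3′ UTR introns, and the dashed line marks the median of all 864 genes at 7.63%.

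Unspliced percentages varied with where the annotated intron lay. Introns in coding sequence had a median of 6.99% over 784 genes, against 7.55% for random lists matched on count (percentile 0). These are most of the 864 measured genes, so each random list held largely the same genes. The percentile mainly restates that the remaining genes were higher, and is not a separate result on coding introns. That call was lost at a minimum of 200 (percentile 14.8). The 13 genes with an intron in the 3′ UTR had a median of 71.6%, against 7.35% for random lists matched on count (percentile 100), and 9 of them lay above 50%. Examples were gsa1 at 93.0% ± 0.325, SPBP22H7.04 at 94.8% ± 0.636 and the vesicle tethering gene trs8502 at 90.7% ± 2.02, while fml2 at 24.2% ± 2.98, rpl39, ero11 at 40.5% ± 1.82 and gap1 at 0% lay below 50%. The 41 genes with an intron in the 5′ UTR had a median of 14.8% against 8.17% (percentile 98.6). They ranged from put2 at 0.467% ± 0.0620 to dao1 at 91.2% ± 2.06, with the stress transcription factor gene atf1, whose intron of 855 nt was the longest, at 44.5% ± 0.336. The 5′ UTR call was lost with list means (percentile 81.9) and at a minimum of 200 (68.9).

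Genes with few exonic counts and genes with long introns had higher unspliced percentages. Over 838 genes with 1 RefSeq intron, the Spearman rho of the unspliced percentage was -0.51 with the exonic count, 0.20 with intron length, 0.29 with intron GC content and 0.17 with the relative position in the mRNA. With the sum of mature and premature counts, which also enters the percentage, it was -0.42. At a minimum of 200 counts the rho was 0.35 with intron length, 0.31 with GC content, 0.13 with position and -0.44 with the exonic count. The introns are not independent replicates, so no p is given. With the introns split by exonic count into 4 bins of like size, the median was 16.0% in the lowest bin, then 8.94% and 5.62%, and 2.40% in the highest. The median was 5.15% for introns over 45 and up to 60 nt (234 introns), 9.48% over 100 and up to 200 nt (178 introns) and 19.8% for the 29 introns over 400 nt. Agreement of the 5′ splice site with the most common hexamer had a rho of 0.01. The 202 introns with GTATGT had a median of 5.21%, against 8.23% for the 306 with GTAAGT. At the 3′ end, 660 introns ending in TAG had a median of 6.76%, 110 ending in CAG 10.9% and 66 ending in AAG 11.3%. These medians kept their order in each library except that CAG was above AAG in replicate 1, at 11.3% and 10.5%.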

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

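The restriction to genes with 1 RefSeq intron, the omission of ribosomal protein genes and random lists matched on exonic count were chosen after seeing the data. A minimum of 20 was reached by 1015 genes and one of 200 by 409. At minimums of 20 and 200 the median unspliced percentage was 8.35% and 3.89%, and 25 genes exceeded 50% at 200. The rho between libraries was 0.915 with no minimum and 0.966 at 200. Scaling by overdispersion, estimated with the called genes included, left 3 genes with a differing unspliced percentage and 18 with differing exonic counts. DESeq2 size factors left 403 exonic calls, and without ribosomal protein genes 5 unspliced calls were left, because 9 of the 14 were removed. The median exonic log2 ratio was -0.00 with TMM and 0.00 with DESeq2 factors, which are both built to bring it near 0.

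The ribosomal protein list stood apart with unmatched random lists (percentile 0) and with matching on exonic count (0.0250), but was at 63.6 with list means and at 15.6 at a minimum of 200. The proteasome list no longer stood apart at minimums of 20 (9.45) and 200 (2.60) or with matching on exonic count (4.06), and ranged from 0.850 to 3.47 over single libraries, failing in replicate 1 alone. Coding introns reached percentile 14.8 at a minimum of 200. Introns in the 5′ UTR reached 81.9 with list means and 68.9 at 200. The meiosis list, the 3′ UTR introns and the genes without a RefSeq intron stood apart under every alternative run on them. A minimum of 200 was not run on the meiosis list, because under 5 members reached it. Those members, mam33, ste24 and map3, were at 5.97%, 3.65% and 0.838%. At minimums of 20 and 200, rho was -0.39 and -0.46 with the sum of counts, 0.19 and 0.35 with intron length, 0.26 and 0.31 with GC content, 0.15 and 0.13 with position, and -0.00935 and 0.0355 with hexamer agreement. With exonic count it was -0.44 at 200. Over single libraries it ranged from -0.42 to -0.39 with the sum of counts and from 0.288 to 0.290 with GC content. Except where stated, the cause was not tested. Among 42 single named genes, 22 moved by 1 SD or more with 0.5 added to both counts, and no gene by more than 0.687 points. A single library or summed counts cannot lie 1 SD from a mean of 2 libraries, and single libraries moved genes by up to 21.3 points (rpl1802).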

Other observations

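Copies of the same ribosomal protein gene could differ widely in unspliced percentage, a comparison chosen after seeing the data. Of 22 families with at least 2 measured copies, 14 had all copies within 2 percentage points and 3 had copies over 10 points apart. The widest pair was rps1701 at 1.75% ± 0.50 (SD, n = 2) and rps1702 at 85.9% ± 13.5, although their exonic counts were similar, at 38760 and 42587 in replicate 1. Their sums of mature and premature counts were less alike, at 6136 and 2069 in replicate 1. The mature count of rps1702 was 94 in replicate 1 and 1161 in replicate 2, so its value is uncertain. The second pair was rpl3001 at 0.867% ± 0.0263 and rpl3002 at 50.2% ± 3.13, where the less spliced copy had 3095 exonic counts in replicate 1 against 44329. The third, rpl1801 at 1.84% ± 0.128 and rpl1802 at 27.0% ± 30.1, rests on replicate 1, since rpl1802 was at 48.2% there and at 5.68% in replicate 2. Among 5′ UTR introns, rps2202, another ribosomal protein gene, was at 45.3% ± 0.598 and the bromodomain gene bdf2 at 39.5% ± 1.03.

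In the weighing that follows, the tests of the unannotated introns, of the abutting exons and of DNA read equally well at every gene were chosen after the result had been seen. No biological explanation was tested for any of the patterns, since the labels give 1 group.

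Ribosomal protein genes took a larger share of exonic counts in replicate 2, with a median log2 ratio 0.30 above that of other genes. A bias by abundance alone, or by the length or GC content of the whole annotated mRNA alone, was argued against by matching. The difference was 0.16 (95% bootstrap interval 0.10 to 0.23) from genes of like abundance. It was 0.24 (0.20 to 0.29) from genes of like mRNA length and 0.19 (0.13 to 0.25) from genes of like mRNA GC content. In a linear fit of all 3 properties together, the ribosomal protein term was 0.14 (0.09 to 0.19). These intervals cover the spread between genes, which are not independent replicates, and not the spread between libraries. Part of the difference followed abundance and these whole-mRNA properties, and they did not account for all of it. Reads start at primers close to introns, and the length and GC content of the fragments read were not known. A bias by those fragment properties was therefore not tested. A difference in growth between cultures may be involved and stays open, as the labels do not say whether the cultures were separate.

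In 4 genes past the Fisher test, rpl1802, rpl8, SPCC16A11.03c and rps1702, the unspliced percentage differed by over 10 points between libraries. Sharing of reads was argued against by sequence: 0% of 413 windows of 25 nt in these introns occurred elsewhere in the genome, and 0% of 41 windows within 50 nt of the rps1702 junction occurred in another mRNA of the files or elsewhere in the genome. Uneven amplification of few molecules may be the source. It stays open, because any use of molecular identifiers is not known. A comparison with genes of like counts was not independent of how these 4 genes were chosen.

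Genes without a RefSeq intron of 20 nt or more were mostly counted as premature, with a median of 98.4% over 23 genes. The lowest were mrpl24 and ats1 at 0%, map3 at 0.838% and rnh202 at 0.910%. Their mature reads may come from introns that RefSeq does not hold, which was not tested. Exons that abut, overlap or lie under 20 nt apart, as RefSeq draws them in cwf22, mrps9 and pdc101, may have been counted as introns: 10 of 11 such genes lay above 90%, against 3 of 12 genes with no break between exons (two-sided Fisher exact p = 0.00276). Counted introns that are not spliced or were withdrawn from the annotation cannot be told apart, because the comparison of 13 of these 23 with 22 of 838 genes with 1 intron above 90% (two-sided Fisher exact p = 6.31e-14) only restates the pattern. Genomic DNA in the libraries cannot be told apart either: over 58 genes without an intron the rho of premature with exonic counts was 0.13, with a wide 95% bootstrap interval from -0.18 to 0.39. Median premature counts in replicates 1 and 2 were 16 and 19 in all 61 genes without an intron. They were 16 and 23 in 749 genes with 1 intron and at least 50 mature counts in each library. These medians do not decide the question, because the 61 genes had no count minimum and the sets are therefore unlike. The 13 genes above 90% had medians of 116 and 163 premature counts in replicates 1 and 2. Of 354 genes with 1 intron and at least 200 mature counts in each library, 66.9% had fewer premature counts than the lowest of those 13 genes. Neither value decides anything, because the 13 were picked by high premature counts.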
